A study of Caenorhabditis elegans with 2 samples.

How the data were processed

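The series is a chromatin immunoprecipitation sequencing (ChIP-seq) experiment on the GATA transcription factor ELT-3 in the nematode Caenorhabditis elegans. Per the labels, whole L3 larvae of strain OP75 were used. This strain has the unc-119(ed3) mutation and carries an integrated transgene, wgIs75, that makes ELT-3 fused to green fluorescent protein. The labels give elt-3 as the antibody's target and describe the experiment as directed at the fusion, so whether the antibody recognised the fluorescent protein or ELT-3 is not settled by the sources used here. The labels name 2 biological replicates of mixed sex, 1 library each, and a fragment size range of 150 to 350, with no unit given. A control experiment is named in the labels and was not used here, so no background was measured independently of the peak calls. There is 1 group of samples and therefore no comparison between conditions.

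The authors deposited peak lists for each replicate and for the pooled replicates, on the ce10 and ce11 genome builds. Per the README text in the deposit, each replicate list was derived from that replicate's alignments and a control, and the pooled list from both replicates' alignments and a control. These relaxed lists hold peaks together with background regions, as input for an irreproducible discovery rate (IDR) analysis. A further list, the IDR list, holds the regions that passed an IDR threshold and was derived from both replicate lists and the pooled list. The aligner, the peak caller, their versions, the IDR threshold and the read depth of the libraries are not given in the sources used here. Intervals on shares below therefore cover counting error over peaks only. The signal value of each region is the authors' own, with a scaling that is not given in the sources used here. Signals and ranks were used to order regions within a list. Signals were also compared between the replicates by correlation and between the builds at equal rank. The −log10 q-value of each region is also as the authors deposited it. It was not used to order regions, because 141 of the 280 peaks of the IDR list on ce11 share the highest value of 2.45.

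The ce11 lists were annotated with the WBcel235 assembly, whose chromosome lengths are those of ce11, and Ensembl release 115 gene models with 19973 protein-coding genes. Coordinates are 1-based on ce11. Lists on ce10 were counted and compared by rank and signal only, and no coordinate was converted. A peak was placed by its summit. A promoter window ran from 1000 bp upstream to 200 bp downstream of the 5′ end of a protein-coding gene. The GATA motif was WGATAR (W is A or T, R is A or G) on either strand within 50 bp of a summit, and the control was the window of the same size centred 500 bp to the right of the summit.

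Shares of summits in promoters, in gene features and near noncoding genes (within 200 bp) were tested by a two-sided permutation test with 10000 circular shifts of the summits along each chromosome. This keeps the spacing of the peaks, and 1e-04 is the smallest p it can give. Matches between the IDR list and the replicate lists are counts only, since the IDR list was made from those lists. Motif shares were compared by the exact McNemar test, and all 6-mers by Fisher's exact test on the presence of the 6-mer in summit and control windows, without regard to strand. The 6-mer test does not use the pairing of a peak's summit window with its own control window. Gene lists were tested by two-sided Fisher's exact test on genes with a summit in the promoter window against all other protein-coding genes. Circular shifts were run beside it, since neighbouring genes can share a summit. Counts per chromosome were set against chromosome length with 100000 multinomial draws and exact binomial tests. Peaks are not replicates, and these tests describe the spread over peaks within this experiment. Tests of one kind were adjusted together by the Benjamini-Hochberg method, and 0.05 was the threshold. Intervals are 95% Wilson intervals for shares and exact conditional intervals for odds ratios. Replicate signals were compared by Pearson's r of log2 signal and Spearman's rho across peaks, with 100000 permutations, or 1000 for all pooled regions.

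There were 16 gene lists, fixed before the data were examined together with the tests, the windows and most of the alternatives. They cover cuticle collagens, other cuticle and moulting genes, hedgehog-related and patched-related proteins, epidermal antimicrobial peptides, epidermal transcription regulators, osmotic and oxidative stress genes, GATA factors, nuclear hormone receptors, heat shock proteins, ribosomal proteins, and markers of intestine, body wall muscle, pharynx, neurons, and germline and sperm. Together they hold 981 genes, of which 13 are in more than 1 list. The names elt-5, daf-21, opt-2 and C44H4.1 matched no gene name in the annotation and were left out. The genes named in the text are those with a summit of one of the 25 strongest IDR peaks in the promoter window, or the gene with the nearest 5′ end where there was none, up to 4 members of each list with an IDR peak, and elt-3 and unc-119. Genes named outside this rule are marked as such. After the data were seen, the lists of ribosomal proteins and cuticle collagens were completed by gene names and RefSeq product names to 88 and 180 genes. The list of other cuticle proteins was widened by gene name classes to 78 genes, not all of which act in the cuticle. These lists were tested again beside the planned ones.

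Chromosomes were divided into blocks of even density of pooled regions by Poisson segmentation of 50 kb bins, with a penalty of 15 per block and at least 10 bins in a block. This step was chosen after the data were seen. Blocks with at least 1.5 times the density of the genome are called raised. Alternatives used the stronger part of the IDR list, the 1000 strongest pooled regions, the 280 strongest regions of each replicate alone, other windows, other motif controls and other tests.

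The main steps were tested on simulated data. Of 200 sets of 280 random summits, 4.5% passed the threshold in the promoter test, 3% in the motif test and 4.5% in the chromosome test, and in 4% at least 1 gene list passed. With TGATAA written into 56 of 280 summit windows, 99.5% of 200 simulations passed the motif test. With X given 1.6 times its weight, 71.5% of 200 simulations passed the chromosome test. With 7 of the 81 ribosomal protein genes given a summit among 19973 genes, that list passed in 100% of 200 simulations. This pass followed from the counts alone, and it does not cover lists with 2 genes at a peak. The random summits were spread evenly along the chromosomes, unlike the peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.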

Results

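Binding sites of ELT-3, a GATA-type transcription factor of the worm epidermis, were mapped by ChIP-seq in L3 larvae with a transgene for ELT-3 fused to green fluorescent protein, in 2 biological replicates of whole animals. The IDR list held 280 peaks on ce11, each 356 bp wide, with signals from 46.8 to 148. It was drawn from relaxed lists of 21761 regions for the pooled replicates and 30000 regions for each replicate. Both replicate lists have this same length on ce10 too, which looks like a fixed limit that the sources used here do not explain, so densities taken from them compare positions within a list and not amounts of binding. The 280 IDR peaks were exactly the 280 strongest regions of the pooled list. Some of them overlap each other, such as ranks 35 and 42, 55 and 79, 64 and 164, and 109 and 192. Each peak was counted on its own below, so the counts are of peaks and not of separate sites. The ce10 IDR list held 292 peaks, which were also the strongest of its pooled list, and over the first 280 ranks the pooled signals of both builds at equal rank differed by at most 0.858%. In replicate 1 they differed by up to 7.23%, with a median of 1.09%, and in replicate 2 by up to 2.27%. The read depth of the libraries was not given in the sources used here.

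The strongest peaks lay at genes of several kinds. The top peak, with a signal of 148, lay between genes on chromosome IV from 13919245 to 13919600, 6394 bp upstream of Y37A1A.2. The peak of rank 2, on chromosome II from 11501952 to 11502307, lay 1671 bp upstream of B0334.20. Rank 3 had its summit 163 bp upstream of cdc-48.1, which encodes a p97-type AAA ATPase, on chromosome II from 10563392 to 10563747 with a signal of 134. Rank 4 lay 260 bp upstream of F45D3.4 on chromosome V, with a signal of 132. Rank 5 lay 283 bp upstream of the ribosomal protein gene rpl-3, on chromosome III from 3867393 to 3867748, with a signal of 125.

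Among the other peaks of the top 25, those with a summit in a promoter window lay at rpl-20 and Y17G9B.5 (1 summit for both), at K01G5.10 and tasp-1, a taspase gene, at puf-9, a Pumilio-family gene, and at F16G10.14, rpl-15 and K11H12.8, tos-1, ska-3 and rps-12, H41C03.3, and rpl-35. Their signals ran from 118 at rpl-20 to 90.5 at rpl-35. Peaks outside any promoter window had their nearest 5′ ends at W02H3.3, ZK899.6, F55G7.5, C41A3.2, hyl-1, K02D3.1, cest-16, T24D8.6, C17G10.7, elt-3 and nhr-14. Of these, the peak nearest to hyl-1 (8388 bp) was in an intron of the cGMP-dependent kinase gene pkg-2. The peak nearest to cest-16 (3366 bp) was in an intron of mom-1, and the peak nearest to C41A3.2 (15227 bp) was in a coding exon of the polyketide synthase gene pks-1. These 3 host genes fall outside the naming rule and were picked after their values were seen.

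ELT-3 peaks were found inside elt-3 itself. Its introns held 3 IDR peaks, 1902, 2626 and 3259 bp downstream of the 5′ end, of ranks 108, 81 and 20. The gene (WBGene00001251) lies on chromosome X from 13934874 to 13941216, and the strongest of the 3 peaks spans 13937955 to 13938310 with a signal of 93.4. Another IDR peak within 20 kb, of rank 46, lay 14301 bp upstream (X, 13920395 to 13920750). The strongest pooled signal within 20 kb of elt-3 was at percentile 99.2 of all protein-coding genes, and the density of pooled regions, 0.755 per kb against a median of 0.210, at percentile 99.9. Of these IDR peaks only that of rank 108 had WGATAR within 50 bp of its summit. Per the labels the strain carries an elt-3 transgene, so the elt-3 values do not separate binding at the native gene from binding at the transgene. Nor do they separate binding from reads of the transgene's own copies of the locus, since the control library was not used here. At unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935), the gene mutated in the strain, no IDR peak lay within 20 kb, and its strongest pooled signal of 28.6 was at percentile 57.1.

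The replicates ranked the IDR peaks differently. Of the 280 IDR summits, 192 (68.6%, interval 62.9 to 73.7) had a summit within 100 bp among the 280 strongest regions of replicate 1, and 136 (48.6%, 42.8 to 54.4) among those of replicate 2. The IDR list was made from these same libraries, so a match above random placement is built in, and these shares are given as description only. In both replicates together, 82 peaks (29.3%) were matched within the 280 strongest, and 108 (38.6%) when any overlapping region counted as a match. The ribosomal protein genes rpl-3, rpl-20, rpl-15 and rps-12 were within the first 69 ranks of both lists, at 11 and 3, 7 and 26, 45 and 12, and 69 and 14 in replicates 1 and 2. The peak at F45D3.4 was the strongest of replicate 1, and in replicate 2 it overlapped the region of rank 29, whose summit was 115 bp away.

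Over the complete relaxed lists, 270 IDR peaks had a summit within 100 bp in replicate 1 and 241 in replicate 2. Of the 39 without a summit in replicate 2, 31 still overlapped one of its regions. Across the 231 peaks found in both, the signals were weakly related, with Spearman's rho = 0.172 (permutation p = 0.00861) and Pearson's r of log2 signal = 0.154 (permutation p = 0.0190). Both correlations are across peaks, which are not independent replicates and which were selected on pooled signal. Selection on a signal that combines both replicates can lower the correlation within the selected set. Low values here and in the other strong sets below therefore do not by themselves show that the replicates disagree. Over the stronger 140 IDR peaks, of which 120 were in both, rho was 0.156 (permutation p = 0.0897) and r 0.0762 (permutation p = 0.406). Over the 1000 strongest pooled regions, of which 751 were in both, rho was -0.00203 (permutation p = 0.956) and r 0.0959 (permutation p = 0.00879). Over all pooled regions, of which 5470 were in both, rho was 0.226 and r 0.387 (permutation p = 1e-03 for each, the smallest possible with 1000 permutations). With the strongest overlapping region of each replicate in place of the nearest summit, 271 IDR peaks were in both, rho was 0.219 (permutation p = 0.000220) and r 0.233 (permutation p = 7e-05). These last 2 settings and the count of 108 were chosen after the data were seen.

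**Figure D1:**
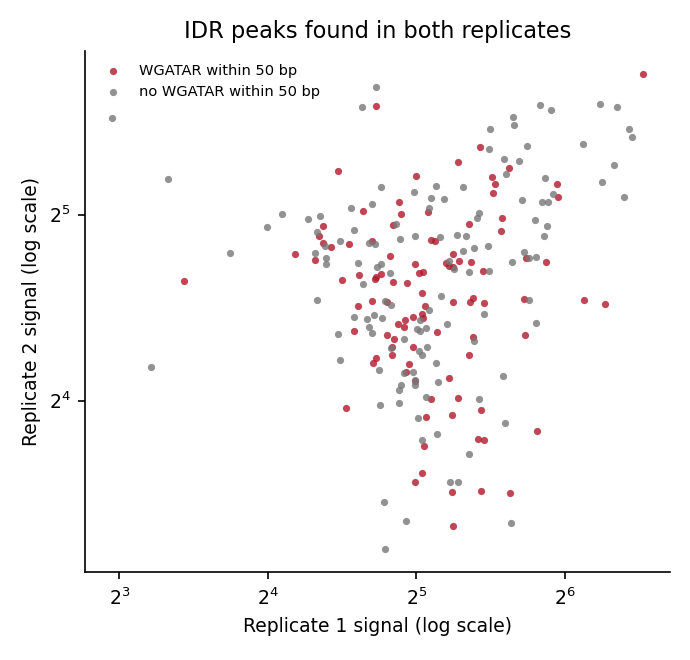
Signal of each IDR peak in replicate 1 (x axis) and replicate 2 (y axis), both as log scales of the authors' signal value; 1 point is 1 of the 231 peaks with a summit within 100 bp in both replicates, coloured by the presence of WGATAR within 50 bp of the summit. The points scatter widely (Spearman's rho = 0.172), with and without the motif. The peaks were selected on pooled signal, which can lower this correlation.

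ELT-3 peaks were concentrated between genes and were rare in coding sequence. Of the 280 summits, 192 (68.6%) lay between protein-coding genes, against 37.4% under circular shifts, and 7 (2.5%) in coding exons, against 24.1% (permutation p = 1e-04 for each, the smallest possible, adjusted 0.000300 over 6 features). Introns held 65 summits (23.2% against 33.5%; permutation p = 0.000400, adjusted 0.000800), and 5′ UTRs held 10 (3.57% against 1.41%; permutation p = 0.00810, adjusted 0.0121). In 3′ UTRs there were 6 summits (2.14% against 3.41%; permutation p = 0.261). The promoter windows of 133 protein-coding genes, 0.666% of all, held a summit.

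By promoter window, 110 summits (39.3%, 33.7 to 45.1) lay from 1000 bp upstream to 200 bp downstream of a 5′ end, such as those at cdc-48.1 and tos-1. Circular shifts gave 20.8% (95% range 16.1 to 25.7), a ratio of 1.89 (permutation p = 1e-04, the smallest possible). The median distance from a summit to the nearest 5′ end was 1382 bp, and 109 summits (38.9%) lay over 2 kb away.

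The GATA motif was more frequent at the summits than beside them. WGATAR was present within 50 bp of 124 of 280 summits (44.3%, 38.6 to 50.1) and in 61 of the windows 500 bp to the right (21.8%, 17.4 to 27). In 99 peaks the motif was in the summit window alone and in 36 in the control window alone (exact McNemar p = 5.5e-08). Peaks with the motif included those near Y37A1A.2, F45D3.4, hyl-1 and cest-16 and those at col-62, lpr-3, nlp-31 and osm-11. The peaks at cdc-48.1, rpl-3, rpl-20, puf-9 and tos-1 and the strongest peak within elt-3 had none in the summit window.

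The motif share fell with rank. In the pooled list it was 39.2% in the 500 strongest regions against 23.2% in control windows (exact McNemar adjusted p = 4.14e-06 over 43 bins), and 32.6% against 19.4% in ranks 501 to 1000 (exact McNemar adjusted p = 4.13e-05). In ranks 1001 to 1500 it was 28% against 21.8% (exact McNemar adjusted p = 0.0892). A further 5 bins at weaker signal passed the threshold, so that 7 of the 43 bins did. In replicate 1 the first 3 bins passed, with 41.0% against 19.8% in the first, and in replicate 2 only the first bin, with 33.2% against 19.2%.

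**Figure D2:**
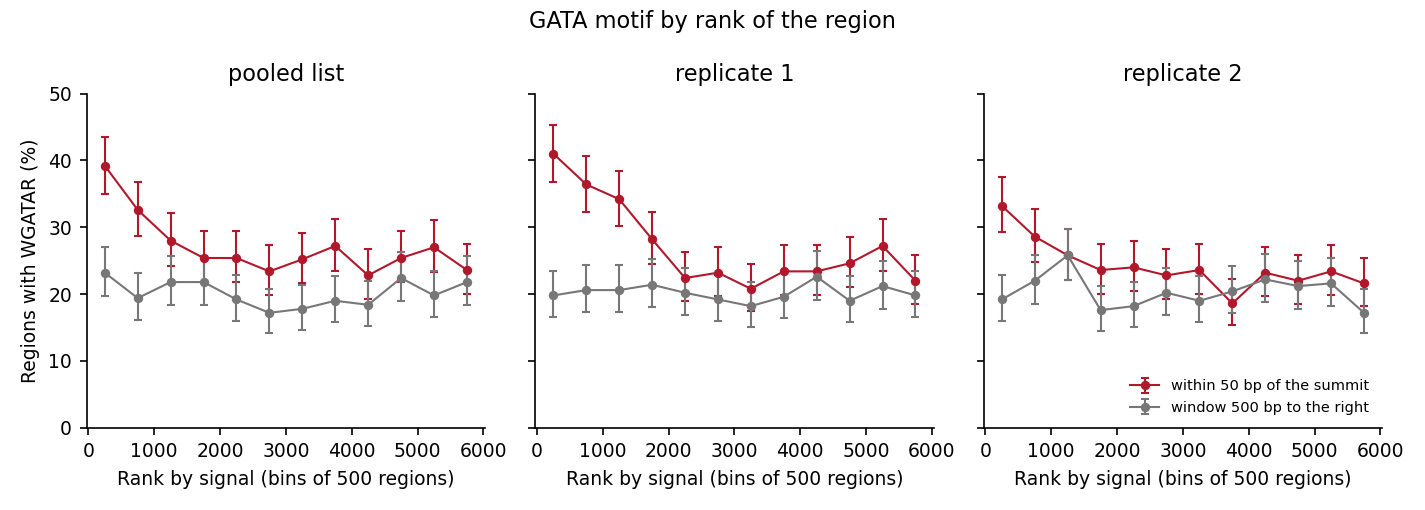
Percent of regions with WGATAR within 50 bp of the summit (red) and in the window 500 bp to the right (grey), against the rank of the region by signal, in bins of 500 regions, for the pooled list and each replicate; bars are 95% Wilson intervals. In the pooled list the share falls from 39.2% in the first bin to 28% in the third, while the control windows stay near 20%.

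Of 2080 6-mers, 52 were more frequent in summit windows and 49 less frequent. The GATA 6-mer CTTATC, the reverse complement of GATAAG, was in 18.9% of summit windows and 3.93% of control windows (Fisher's exact test, adjusted p = 6.03e-06), and TGATAA in 24.6% and 9.64% (adjusted p = 0.000369 by the exact test). Of the 4 6-mers that make up WGATAR, AGATAG also passed (7.86% and 1.79%, exact adjusted p = 0.0288), and AGATAA (13.6% and 7.14%) and CTATCA (12.5% and 6.43%) did not (exact adjusted p = 0.188 and 0.202). Another group shared the core ACGC. ACGCAG was in 26 summit windows (9.29%) and no control window (exact adjusted p = 6.03e-06), and GACGCA in 11.4% and 0.714% (exact adjusted p = 8.69e-06). GAGAGA was in 18.6% and 5.36% (exact adjusted p = 0.000206). CACGTG, an E-box, was in 9.29% and 1.43% (exact adjusted p = 0.00234). A and T runs were less frequent, with AAAATT in 14.6% of summit windows and 44.3% of control windows (exact adjusted p = 2.26e-11), and the windows differed in GC content, 41.8% at summits and 34.9% beside them. With the 280 strongest regions of replicate 2 alone, 9 6-mers passed. Of these, 4 were more frequent in summit windows, 3 of them with GATA on either strand. Most of the more frequent 6-mers without GATA named above thus did not pass in replicate 2. With those of replicate 1 alone, 103 passed, 56 of them more frequent and 7 of these with GATA.

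Ribosomal protein genes were over-represented among the genes with an ELT-3 peak in the promoter window. Of the 81 ribosomal protein genes of the planned list, 7 had one (8.64%), against 126 of 19892 other genes (0.633%), an odds ratio of 14.8 (5.65 to 33; Fisher's exact test, adjusted p = 1.83e-05 over 16 lists). The strongest were rpl-3, rpl-20, rpl-15 and rps-12, with signals of 125, 118, 94.5 and 91.2 and summits 156 to 348 bp upstream of the 5′ ends. Circular shifts gave 0.253 summits in these windows against 7 observed (permutation p = 1e-04, the smallest possible, adjusted 0.00160). The shifts do not take the concentration of peaks in promoter windows into account. Rotation of the peaks along the gene order keeps the number of genes with a peak and was chosen after the data were seen. It gave 0.597 ribosomal protein genes on average against 7 observed (permutation p = 1e-04, adjusted 0.00160). The planned name pattern missed some ribosomal protein genes, among them rpl-7A, whose promoter window holds the peak of rank 230. With the list completed by gene and product names, chosen after the data were seen, 8 of 88 genes had a peak against 125 of 19885 others, an odds ratio of 15.8 (6.46 to 33.6; exact adjusted p = 2.06e-06).

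The lists for epidermal antimicrobial peptides and for osmotic and oxidative stress genes also passed, each on 2 genes. The antimicrobial peptide genes nlp-31 and nlp-34 (2 of 21, odds ratio 15.9, 1.78 to 67.1; Fisher's exact test, adjusted p = 0.0497) shared a single summit, 18 bp and 903 bp upstream of their 5′ ends, with a signal of 60.3. Counted as 1 summit, it gave a permutation p = 0.0474, adjusted 0.253, by circular shifts. The stress list was represented by osm-11, a secreted regulator of the osmotic response, with a signal of 76.3, and wdr-23, a repressor of the SKN-1 stress response, with a signal of 56.4 (2 of 22, odds ratio 15.1, 1.70 to 63.3; exact adjusted p = 0.0497; circular-shift permutation, adjusted p = 0.0168). With the 280 strongest regions of replicate 1 alone both lists missed the threshold at odds ratios of 15.3 and 14.6 (exact adjusted p = 0.0533 for each). With those of replicate 2 alone the antimicrobial peptides passed (odds ratio 19.1, exact adjusted p = 0.0480) and the stress list had 1 gene (odds ratio 8.59, exact adjusted p = 0.369). In replicate 2 the osm-11 peak matched the region of rank 4182. The wdr-23 peak had no summit within 100 bp there and overlapped the region of rank 1119. For the stress list, rotation of the peaks along the gene order gave 0.156 genes on average, and the circular shifts 0.0664 summits. Both lists missed the threshold too with this rotation (permutation, adjusted p = 0.0688 for each, chosen after the data were seen). The stress list also missed it without the raised blocks of chromosome I, where wdr-23 lies (exact adjusted p = 0.621, chosen after the data were seen).

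The planned lists of cuticle genes did not pass. Of 176 cuticle collagens only col-62 had a summit in the promoter window (signal 67.0, odds ratio 0.851, 0.0213 to 4.89), and of 62 genes for collagen processing, moulting and other cuticle proteins only lpr-3, a lipocalin-related gene (signal 62.3, odds ratio 2.46, 0.0607 to 14.4); the adjusted p was 1 for both by the exact test. The second of these lists had left out dpy-31 and dpy-6, which have the peaks of rank 140 and 95 in their promoter windows. Widened by all other genes named dpy, bli, rol, sqt or lon that are not collagens, a class named for body shape that also holds genes for dosage compensation such as dpy-27, it had 3 of 78 genes with a peak (odds ratio 6.08, 1.21 to 18.9; exact p = 0.0153, adjusted 0.0611, chosen after the data were seen). Of 274 nuclear hormone receptors, nhr-68 and nhr-80 had a summit in the promoter window (signals 73.9 and 57.5, odds ratio 1.1, exact adjusted p = 1). The other 10 lists had no member with a summit in the promoter window: hedgehog-related and patched-related proteins, epidermal transcription regulators, GATA factors, heat shock proteins, and the markers of intestine, body wall muscle, pharynx, neurons, and germline and sperm. Introns, which this test does not cover, held 5 summits in the nuclear hormone receptor genes nhr-14, nhr-19, nhr-23 and nhr-91, and 4 in the GATA factors elt-3 and egl-27; elt-3, egl-27 and nhr-23 are also on the list of epidermal regulators. These genes other than elt-3 were picked after their values were seen. No chance level was computed for the intron counts. The summits of ranks 20, 81 and 108 among them are in elt-3, whose locus the transgene carries. A promoter count of 0 in these lists leaves room for an odds ratio of up to 6.52 for the 87 germline and sperm markers and up to 54.3 for the 12 GATA factors.

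**Figure D3:**
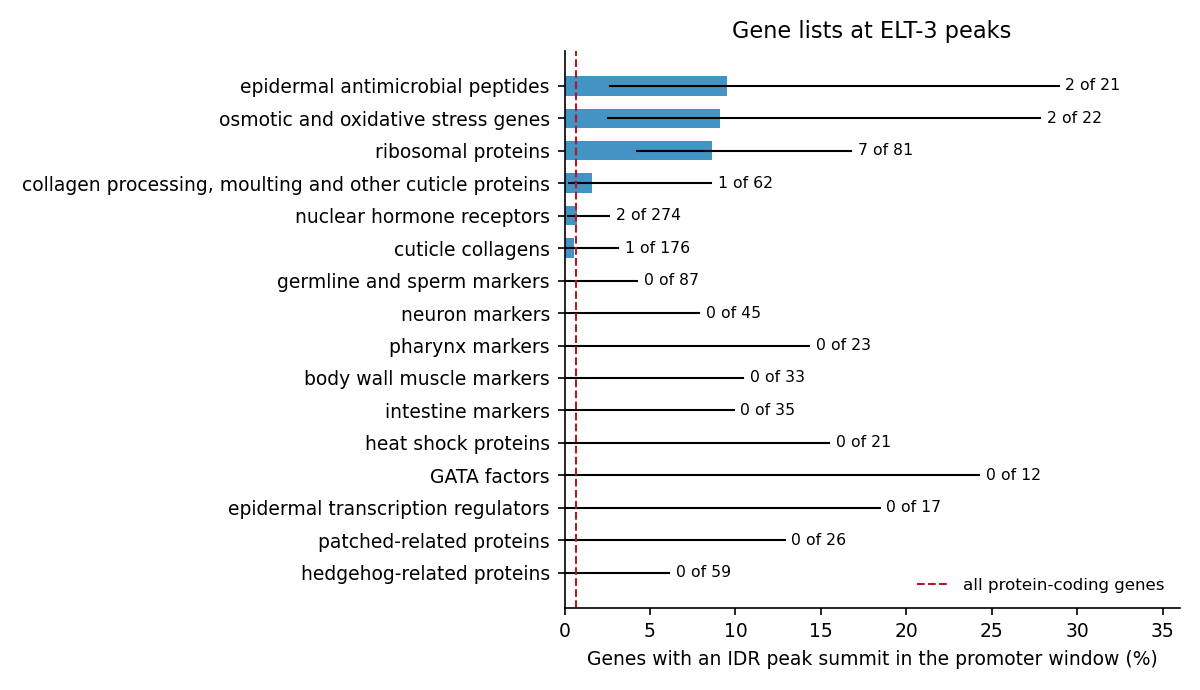
Percent of the genes of each list with an IDR peak summit in the promoter window (bars, with 95% Wilson intervals as lines and the counts beside them); the dashed line is the share over all protein-coding genes, 0.666%. Ribosomal proteins (7 of 81), antimicrobial peptides (2 of 21) and stress genes (2 of 22) stand above the line by more than their intervals. The 2 antimicrobial peptide genes share 1 summit. No member with a summit in that window was found in 10 lists.

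Of 5 classes of noncoding genes, small nuclear RNA genes were found near peaks more often than under circular shifts. They had 4 summits within 200 bp against 0.151 under circular shifts (permutation p = 1e-04, the smallest possible, adjusted 0.000500), at the SL2 spliced leader genes sls-2.1 (rank 23) and sls-2.4 (ranks 35 and 42) and at sup-6 (rank 149), all picked after their values were seen. The peaks of ranks 35 and 42 overlap and lie in the promoter window of egg-5, also picked afterwards. Rank 23 lies in that of H41C03.3. The shifts do not take the concentration of peaks between genes into account, so they do not separate a class from its position. There were 2 summits at tRNA genes (against 0.909; permutation p = 0.234, adjusted 0.391) and 2 at snoRNA genes (against 0.505; permutation p = 0.0914, adjusted 0.228), and none at microRNA or rRNA genes. The small nuclear RNA genes had 3 summits with replicate 1 alone, 2 with replicate 2 alone and 2 without the raised blocks of chromosome I (permutation, adjusted p = 0.00500, 0.0445 and 0.0430, the last chosen after the data were seen). With a distance of 500 bp, or with replicate 2 alone, snoRNA genes passed too (permutation, adjusted p = 0.00275 and 0.0445).

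Chromosome X held more IDR peaks than its length predicts. It had 81 of 280 peaks (28.9%, 23.9 to 34.5) with 17.7% of the genome, a ratio of 1.64 (exact binomial p = 4.43e-06, adjusted 2.66e-05 over 6 chromosomes), and all chromosomes together departed from length (permutation by multinomial draws, p = 2e-05). Of the 25 strongest peaks, those at puf-9, elt-3 and nhr-14 were among the peaks on X. Chromosome IV had 30 peaks (ratio 0.614, exact binomial adjusted p = 0.00625) and chromosome V 39 (ratio 0.667, adjusted p = 0.00800 by the exact test). Chromosomes I, II and III had 48, 38 and 44 peaks (ratios 1.14, 0.891 and 1.14, exact adjusted p from 0.407 to 0.506). The middle 50% of the chromosomes' length held 169 peaks (60.4%, exact binomial p = 0.000632 against 50%), and the pooled regions had 58.0% there, from which the IDR peaks did not differ detectably (exact binomial p = 0.468).

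The 2 replicates differed in chromosome I. Of their 280 strongest regions, replicate 1 had 33 on chromosome I and replicate 2 had 83. The relaxed lists had more regions per megabase in 3 blocks of this chromosome, from 1 to 2550000, from 2550001 to 4850000 and from 6500001 to 7900000, which make up 6.23% of the genome. Pooled regions numbered 405 per megabase in these blocks and 205 elsewhere, replicate 1 had 487 and 287, and replicate 2 had 479 and 287. The blocks held 40 of the 280 IDR peaks (14.3%), among them those at col-62 and wdr-23, and 73 of the 280 strongest regions of replicate 2 (26.1%) against 29 of those of replicate 1 (10.4%).

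**Figure D4:**
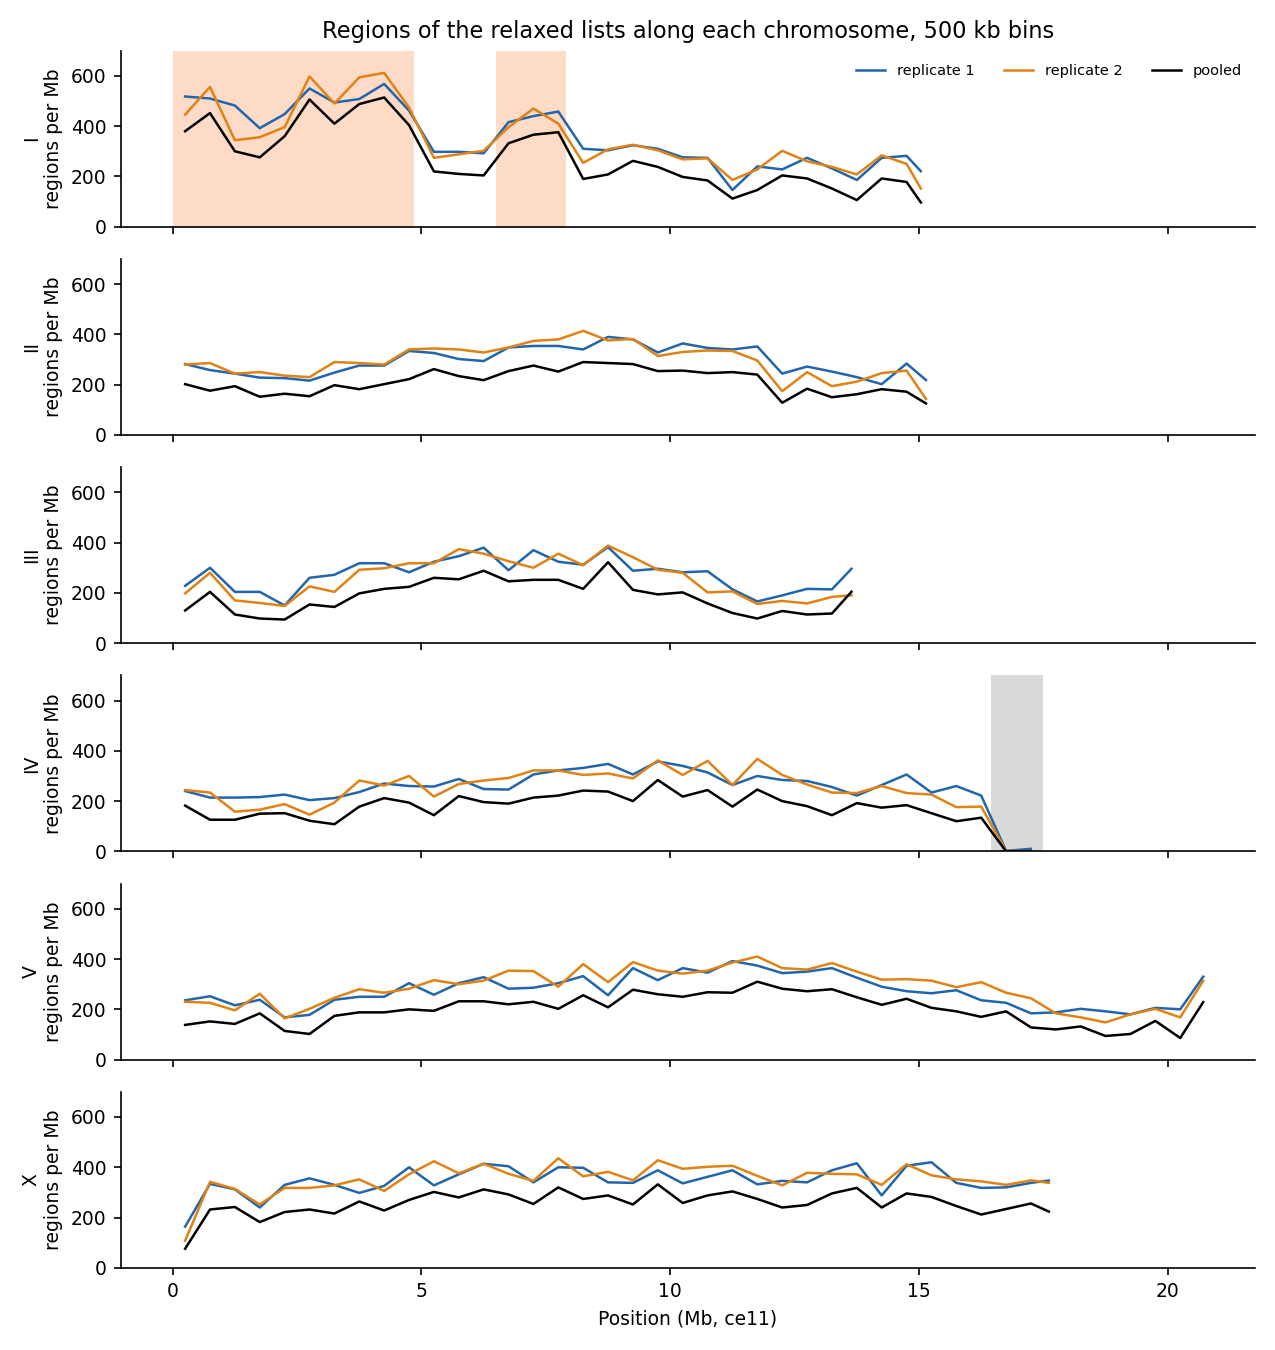
Regions per megabase of the relaxed lists along the 6 chromosomes (x axis, position in Mb on ce11), in bins of 500 kb, for replicate 1 (blue), replicate 2 (orange) and the pooled list (black). Pink bands mark the blocks of chromosome I with at least 1.5 times the pooled density of the genome, and the grey band a block of chromosome IV with 1 pooled region.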

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

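Without peaks in the raised blocks of chromosome I, without peaks near elt-3, with rotation along the gene order, with completed or widened gene lists, with the strongest overlapping regions and with the complete relaxed lists are alternatives chosen after the data were seen; the rest were planned. The 280 strongest pooled regions are the IDR peaks themselves, so this planned setting, for 7 results, could not differ and is not counted. The 14 alternatives for the replicate match are not counted either. Of the other 68 over 12 results, 50 kept the result by the rules used here. Single tested values had to keep the direction and the side of the threshold. Counts and values without a test had to stay within 1.5 times the count or the spread between replicates. Numbers of 6-mers, gene lists, noncoding classes and rank bins that passed were judged as counts. A fall from 3 gene lists to 2 is therefore among the 50, and most gene list alternatives had such a fall. All alternatives kept the direction and the side of the threshold for the promoter share (29.3% to 51.1%), the motif excess at summits (11.4 to 26.4 percentage points), and the X ratio (1.32 to 2.06). The match of IDR peaks was 62.1% to 96.4% to replicate 1 and 44.3% to 86.1% to replicate 2, and its excess over random placement is built in. Spearman's rho between replicates was 0.156 in the stronger 140 IDR peaks, -0.00203 in the 1000 strongest pooled regions, 0.226 in all pooled regions and 0.219 with the strongest overlapping regions. The number of 6-mers passing, 101, became 28 with the stronger 140 peaks and 256 with 1000 regions, which differ in the number of windows tested, and ran from 9 to 103 with a replicate left out. Of 3 gene lists passing, 1 remained with the nearest 5′ end within 5000 bp and 1 with rotation along the gene order (ribosomal proteins each time), and 1 to 2 with a replicate left out. Ribosomal proteins passed in all 9 alternative settings of Fisher's exact test, at odds ratios of 5.72 to 30.2. The antimicrobial peptides lost the call in 3 of the 8 that could change theirs and the stress genes in 7. The number of noncoding classes passing, 1, became 3 with the 1000 strongest regions and 2 within 500 bp, and was 1 to 2 with a replicate left out. The leading rank bins with a motif excess numbered 1 to 3 with a replicate left out, against 2. The central share of 60.4% lost its call against the pooled regions as background. The percentile of the elt-3 locus was 98.4 to 99.3 with a replicate left out. That of unc-119, 57.1, was 10.8 within 10 kb and 11.5 to 28.4 with a replicate left out. The stricter set, at or above the median signal, holds 140 peaks by construction. Otherwise the cause was not tested. The IDR score column is 0 throughout, so a threshold on it was not run, and the replicate match and correlation give no value with a replicate left out. No paired analysis was possible because there is 1 group. Read depth was not given in the sources used here, so how far it limits the lists is not known.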

Other observations

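The comparison of peaks with and without the motif, the further noncoding classes, and the tests of gene density, of the motif excess over control windows, of GATA sites at ribosomal protein promoters, of other housekeeping families on the completed list and of the elt-3 locus were chosen only after the result was seen. The 1000 strongest pooled regions, which include the IDR peaks, placed a summit in the promoter window of 395 protein-coding genes (1.98%), against 133 (0.666%) for the IDR peaks alone. Epidermal antimicrobial peptides had 4 of 21 genes, nlp-31, nlp-34, nlp-24 and cnc-8, an odds ratio of 11.8 (2.87 to 36.3; Fisher's exact test, adjusted p = 0.00552 over 16 lists). These 4 genes share 3 summits, since nlp-31 and nlp-34 have the same one. Cuticle collagens had 7 of 176, among them dpy-5, rol-6, dpy-9 and col-167 (odds ratio 2.07, 0.815 to 4.4; exact adjusted p = 0.241), and collagen processing and moulting genes had 4 of 62, namely nekl-2, nas-36, dpy-11 and lpr-3 (odds ratio 3.44, 0.903 to 9.37; exact adjusted p = 0.183). Of 17 epidermal regulators only grh-1 had a summit, 856 bp upstream (exact adjusted p = 0.658). Of the epidermal lists only the antimicrobial peptides passed, ribosomal proteins passed too, and the stress list, which passed in the IDR set, did not (odds ratio 4.98, exact adjusted p = 0.235). Hedgehog-related proteins, GATA factors, heat shock proteins, and the intestine, body wall muscle, pharynx, neuron, and germline and sperm markers had no member with a summit, and patched-related proteins had 1 of 26. These zeros leave room for odds ratios of up to 2.15 for the germline and sperm markers and up to 17.9 for the GATA factors. These genes were named after their values were seen.

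Of 124 IDR peaks with WGATAR, 40 (32.3%) lay in a promoter window, and of 156 without it, 70 (44.9%), an odds ratio of 0.586 (0.347 to 0.983; Fisher's exact p = 0.0365, adjusted 0.128 over 7 properties, which misses the threshold). Of the 7 properties the smallest p was that of ribosomal protein promoters, with 0 peaks with the motif and 7 without (Fisher's exact p = 0.0187, adjusted 0.128), or 1 and 7 with the completed list (exact p = 0.0807). Of 5 classes beyond the planned ones, genes annotated as ncRNA had 39 summits within 200 bp, against 10.6 under circular shifts (permutation p = 1e-04, the smallest possible, adjusted 0.000500), lincRNA genes 4 against 0.916 (permutation, adjusted p = 0.0307) and pseudogenes 1 against 9.89 (permutation, adjusted p = 0.0227). Antisense RNA genes had 0 and piRNA genes 3, and neither passed (permutation, adjusted p = 1 and 0.285). Here too the shifts do not take the concentration of peaks between genes into account. The right end of chromosome IV, from 16450001 to 17493829, had 1 pooled region, 8 of replicate 1 and 1 of replicate 2, where the genome's mean density gives 227, 312 and 312, though it holds 168 protein-coding genes.

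The first pattern is the raised density of regions in blocks of chromosome I, at a ratio of 1.98 in the pooled list. The ratio fell with signal, from 2.80 in the 7253 strongest pooled regions to 1.66 in the next 7253 and 1.54 in the 7253 weakest. In the 1000 strongest it was 3.76. The replicates differed in this trend. In replicate 1 the ratio was 1.70 over the relaxed list and 1.74 in its 280 strongest regions. In replicate 2 these ratios were 1.67 and 5.31, so at this depth the rise with signal was seen in replicate 2 only. Gene density is argued against, since the blocks have 0.840 times as many protein-coding genes per megabase as the rest of the genome. WGATAR sites are likewise fewer there, at 0.846 times the density of the rest. Background coverage raised across the blocks stays open: among the 1000 strongest pooled regions the motif share was lower in the blocks, 23.5% against 39.0%, a difference of -15.5 percentage points (-21.8 to -8.34; Fisher's exact p = 3.53e-05), but so was the share in control windows, 15% against 22.9%, and the excess of summits over control windows differed by -7.63 points (permutation p = 0.130); in the IDR peaks the share was 35% against 45.8% (exact p = 0.231) and the excess differed by 0. The control library was not used here, and no biological explanation beyond the density of GATA sites was tested.

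The second pattern is the set of ribosomal protein promoters, on lists completed by gene and product names after the data were seen. Of 17 such promoter peaks among the 1000 strongest pooled regions, 2 had WGATAR within 50 bp (11.8%, interval 3.29 to 34.3). Most of them thus lacked the motif near the summit, which argues against WGATAR within 50 bp as the reason for most of these peaks. The values do not cover sites farther from the summit. Of 322 other promoter peaks, 106 had the motif (32.9%), a difference of -21.2 percentage points (-31.2 to 1.94, Fisher's exact p = 0.106). Whether the share is lower than at other promoters stays open. The planned list, which lacked rpl-7A, gave 1 of 16 (Fisher's exact p = 0.0261). Recovery of strongly transcribed housekeeping promoters in general also stays open: translation factor, V-ATPase, ATP synthase, actin and tubulin genes had 4 of 71 with a summit on the list as first written (odds ratio 2.98, 0.785 to 8.05; exact p = 0.0521) and 6 of 114 once it was completed after a peak at iff-2 had been seen (odds ratio 2.78, 0.992 to 6.31; exact p = 0.0258), against 12.4 (6.75 to 21.4) for ribosomal proteins. No biological explanation other than GATA sites was tested.

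The third pattern is the excess of peaks on chromosome X. The elt-3 locus carried by the transgene does not account for it, since without the peaks within 20 kb of elt-3 the ratio was 1.58 (1.3 to 1.89; exact binomial p = 2.54e-05, 77 of 276 peaks). Raised background across X cannot be told apart from more binding: the motif share was 43.2% on X and 44.7% on autosomes, a difference of -1.51 percentage points whose interval runs from -13.9 to 11.3 (Fisher's exact p = 0.895). The pooled regions were also more frequent on X, at 1.25 times its length share in the 7253 strongest regions of the list and 1.17 times in the 7253 weakest. No biological explanation was tested.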
